A study of Mus musculus with 6 samples.

How the data were processed

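RNA from 6 samples of the mouse hepatocyte line AML12 was sequenced, 3 that had received a scrambled RNA (siNC) and 3 that had received an siRNA against Setdb1 (siSetdb1). Per the labels' protocols, RNA was taken 72 h after transfection with siRNA at a stated amount of 50 (the unit is written as nm), mRNA was selected with oligo(dT) beads, cDNA was primed with random hexamers, and single-end reads of 50 bases were made on a BGISEQ-500 instrument. The protocol names no step that marks strand, so reads of overlapping or antisense genes may be counted for either gene. The submitters' processing notes list HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 and the genome build mm10, with no role or order for any of them.

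The deposited table holds 1 value per gene and sample for 25416 genes, with an Ensembl gene ID, a symbol, a biotype, a position and Gene Ontology terms for each gene. Its headers name no unit. The values were found to be FPKM made by the authors before deposit: each gene's values are whole multiples of 1 step per gene and sample, and that step equals the value of 1 read over the summed length of the gene's exons and over 1 total per sample. The exon lengths are those of GENCODE M21 (GRCm38, the assembly of mm10), in which 25372 of the gene IDs were found. With these lengths whole reads within a tolerance of 0.01 came out for 98.6% of the genes, and for the other 346 genes whole reads were fixed only up to a common factor. The recovered totals were 16790582 to 17835060 reads per sample, and all listed reads summed to nearly these totals. No gene in the table was at 0 in each of the 6 samples. FPKM divides by gene length and by the total of a sample, so a gain of reads in a few abundant genes lowers the values of the rest, and reads that fit more than 1 gene copy depend on the authors' unstated treatment of them.

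Samples were assigned to groups from their titles. Both groups carry replicate numbers 1 to 3, but no label says that a number joins samples, and the fit with the number as a block was an alternative. Within each group, pairs of libraries differed by more than counting noise (chi-square per degree of freedom of 5.4 to 28.6), so that no library was counted as a copy of another. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The unit forced changes to that plan. Because the deposited values are FPKM, the planned count test and its DESeq2 alternative were not used, and the test planned for this case, limma-trend, took their place. On the recovered reads, which a count test could also have used, limma-voom was run as an alternative. The filter at 0.5 FPKM was not part of the plan and was set once the unit was known.

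Each gene with at least 0.5 FPKM in 3 or more libraries was tested (12846 genes, with 12570 left out) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity-dependent and robust prior variance and group as the only term. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A change of at least 2-fold means a log2 fold change of 1 or more in size on this scale. The same settings were run on simulated reads for the real genes and totals, in 10 runs with 200 genes changed in each and a median of 12859 genes tested. In these runs 12.8%, 67.8%, 88.4% and 92.6% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold were found, and 12% of all calls (179 of 1487) were false, above the nominal share. Every simulated gene had the same relative spread beyond counting noise, the median of the real genes, and no library was made to stand apart. The shares in the real data, where genes differ in spread, may therefore be different. With the variance trend fitted on mean log2 reads in place of FPKM, 5.32% of calls (80 of 1505) were false, and this fit was added as an alternative. In a simulation with 26 random lists and 1 list of 30 genes shifted by 0.4 on the log2 scale, camera and fry called the shifted list and camera called 0 of the random lists. The simulated genes were drawn independently of each other. The simulation therefore cannot show how camera behaves where the genes of a list vary together. In the real lists the estimated correlation between genes reached 0.61 (DNA replication genes).

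There were 31 gene lists, of which 27 had at least 5 tested members. They were tested with limma's camera with a preset correlation between genes of 0.01, with camera with an estimated correlation and with fry, each adjusted over the 27 lists. These tests used log2(FPKM + 1) in place of the voom weights of the plan. The lists cover the H3K9 methylation machinery, germline genes, imprinted genes, clustered protocadherins, zinc finger genes, interferon-stimulated genes, nucleic acid sensors, hepatocyte products, hepatocyte transcription factors, biliary and progenitor markers, fetal liver and tumour markers, p53 targets, mitosis, DNA replication, senescence, apoptosis, TGF beta response and matrix, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, stress responses, NF-kB and inflammation, NRF2 and glutathione, Wnt targets, EGFR and ERK, macrophages, endothelium, stellate cells, ribosomal proteins, the mitochondrial genome and oxidative phosphorylation.

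The genes named are Setdb1, its partners Trim28 and Atf7ip, and Trp53. They also include the 12 largest changes in each direction among genes that passed, with a mean of at least 1 CPM (recovered reads scaled to library total), no overlap between the groups and an ordinary symbol. From each list up to 4 members with the smallest p among those that passed are taken, or the member with the highest mean where none passed, and not each gene so picked is described. Genes named outside this rule are marked as chosen after their values were seen. Among all genes tested, 39.2% had groups that did not overlap, against the 10% that chance gives for 3 against 3.

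The alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 1 CPM, limma-voom on recovered reads, the replicate block, removal of trends with GC content and gene length by a smooth curve per library (span 0.3, with 99.7% of genes having both values), an adjusted p of 0.01, and leaving out each library in turn. Median-ratio and upper-quartile scaling and the variance trend on reads were added later. Terms for biological processes were tested over 10058 genes with one-sided Fisher's exact tests. Reads were recovered in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.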

Results

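AML12 is a mouse hepatocyte line whose donor animal carried a transgene for human transforming growth factor alpha, a ligand of the epidermal growth factor receptor (EGFR). The cells received a scrambled RNA (siNC, n = 3) or a small interfering RNA against Setdb1 (siSetdb1, n = 3), and polyadenylated RNA was sequenced 72 h later. Setdb1 encodes a methyltransferase that places repressive marks on lysine 9 of histone H3, and the single comparison of the design asks which transcripts differ when its mRNA is reduced. The libraries held 16790582, 17401848 and 17178200 reads in siNC and 17274695, 17073231 and 17835060 reads in siSetdb1, with 19731 to 20544 genes above 0 in each library. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Fold changes are given as log2 of siSetdb1 over siNC on the log2(FPKM + 1) scale, which understates the change of genes with low values, and FPKM values are given as mean ± SD over 3 libraries.

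Setdb1 mRNA was lower in each siSetdb1 library than in each siNC library. Setdb1 (ENSMUSG00000015697) lies on chromosome 3 at positions 95323525 to 95357202 of mm10, on the minus strand, and its value over all annotated exons was 8.41, 8.54 and 9.43 FPKM in siNC against 4.29, 4.21 and 3.29 FPKM in siSetdb1. The mean fell by 55.3%, from 8.80 ± 0.55 to 3.93 ± 0.56 FPKM, with a log2 fold change of -0.995 (SE 0.10, adjusted p = 0.00183, limma). Between 402 and 1110 reads per library stood behind these values. The SETDB1 partner Atf7ip, which stabilises the enzyme in the nucleus, rose from 3.17 ± 0.06 to 4.90 ± 0.35 FPKM (log2 fold change 0.50, adjusted p = 0.00689). Trim28, the corepressor that recruits SETDB1 to zinc finger proteins, had 92.1 ± 8.7 and 78.6 ± 2.0 FPKM, and Trp53 had 49.5 ± 5.5 and 41.7 ± 3.4 FPKM. Neither of these 2 genes passed the test (adjusted p = 0.105 and 0.136).

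**Figure D1:**
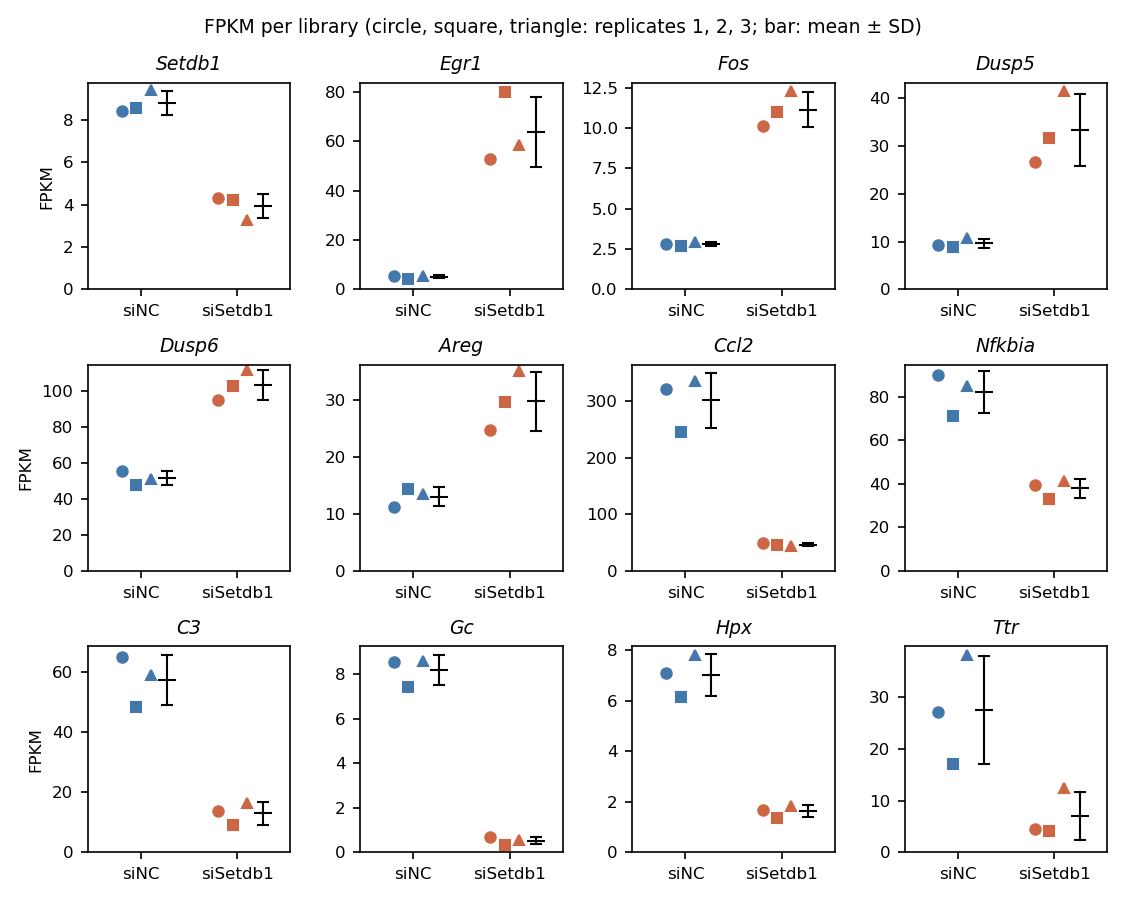
FPKM of 12 genes in each of the 6 libraries, with siNC in blue, siSetdb1 in orange, 1 symbol per replicate number and black bars for the mean and SD of 3 libraries. Setdb1 lies between 3.29 and 4.29 FPKM in siSetdb1 and between 8.41 and 9.43 FPKM in siNC. Among the plotted genes that fell, Ttr has the widest spread relative to its mean.

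Genes changed in both directions in the knockdown libraries. Of 12846 genes tested, 1945 passed, of which 883 rose and 1062 fell, and 98 changed at least 2-fold. The largest rise on the log2(FPKM + 1) scale was that of Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), an immediate-early transcription factor, from 5.08 ± 0.60 to 63.6 ± 14.3 FPKM (log2 fold change 3.39, SE 0.16, adjusted p = 0.000139). By the ratio of FPKM means, Acta1 and Prl2c3, which had low values in siNC, rose further. Gsta1 (ENSMUSG00000074183, chromosome 9, 78230656 to 78242684), an alpha-class glutathione transferase, rose from 9.30 ± 1.07 to 51.5 ± 1.9 FPKM (log2 fold change 2.35, adjusted p = 9.12e-05). Serpinb5, a serpin of epithelial cells, rose from 0.678 ± 0.210 to 7.36 ± 0.44 FPKM. Resf1, a factor that works with SETDB1 in silencing retroelements, rose from 10.9 ± 4.6 to 45.1 ± 3.7 FPKM (log2 fold change 2.04, SE 0.29), with siNC replicate 1 at 5.62 FPKM and the other siNC libraries at 13.0 and 14.2 FPKM. The cytokine gene Il24 rose by 1.76, Sdcbp2 by 1.64, and the skeletal muscle actin gene Acta1 by 1.79 on the log2 scale, the last from 0.0504 to 2.73 FPKM. Prl2c3 (1.99) and Prl2c2 (1.59), like Gsta1 and Gsta2 (1.65), are near-identical paralogs, so that the split of reads between the members of each pair is uncertain.

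Among the genes that fell, Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), a monocyte chemokine, had the largest change on the log2(FPKM + 1) scale, from 302 ± 48 to 46.5 ± 2.6 FPKM (log2 fold change -2.66, SE 0.12, adjusted p = 0.000116). By the ratio of FPKM means, Gc and H2-M2 fell further. Gc (ENSMUSG00000035540, chromosome 5, 89417522 to 89457898), the plasma carrier of vitamin D, fell from 8.18 ± 0.67 to 0.529 ± 0.171 FPKM (log2 fold change -2.59), and complement C3 (chromosome 17, 57203970 to 57228136) fell from 57.3 ± 8.4 to 13.0 ± 3.8 FPKM (log2 fold change -2.08). H2-M2, a nonclassical class I gene, fell from 2.76 to 0.296 FPKM, and Depp1, a target of FOXO factors, fell from 11.8 to 4.17 FPKM. Depp1 had an adjusted p of 0.052, 0.0575, 0.067 and 0.0524 without siNC replicate 1, siNC replicate 2, siSetdb1 replicate 2 and siSetdb1 replicate 3. The count of genes that passed was 1060, 689, 683 and 978 without siNC replicate 2 and without siSetdb1 replicates 1, 2 and 3, and 890 with no filter on low values. The count of 2-fold changes was 273 with a pseudocount of 0.1 and 293 with limma-voom on recovered reads, and 1450 genes rose and 1266 fell after trends with GC content and gene length were removed. With median-ratio scaling 1019 rose and 907 fell, so that more genes rose than fell under both of these settings.

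**Figure D2:**
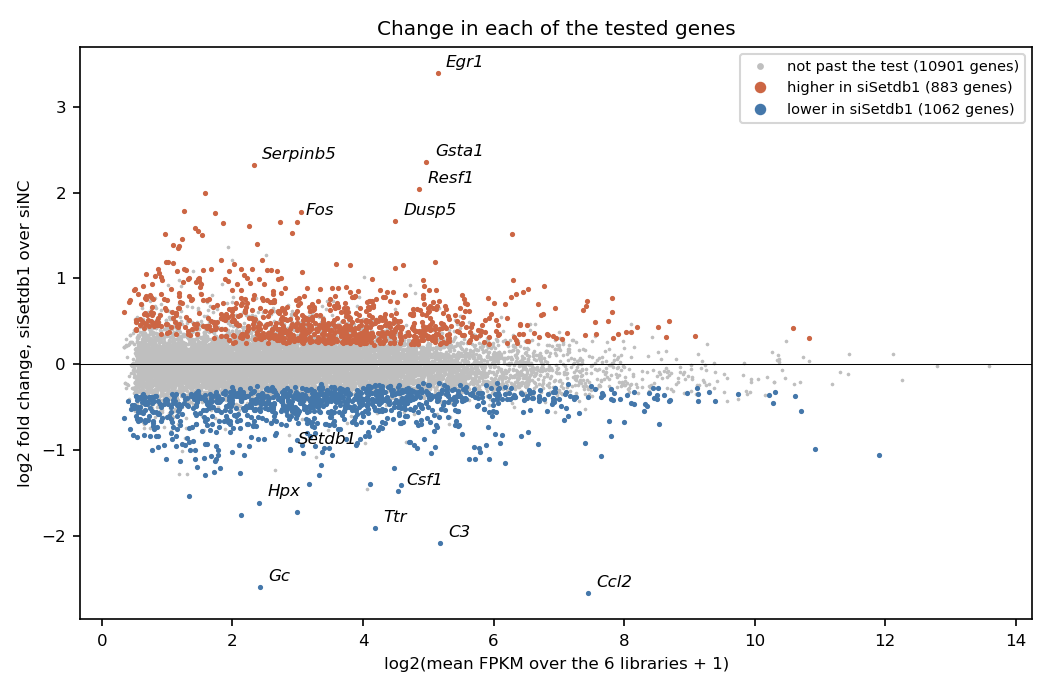
Log2 fold change of siSetdb1 over siNC against log2 of the mean FPKM over 6 libraries plus 1, with 1 point for each of the 12846 genes tested. The 883 genes that rose are orange, the 1062 that fell are blue and genes that did not pass are grey, and Egr1 (3.39) and Ccl2 (-2.66) mark the extremes.

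The libraries did not differ by group alone. siNC replicate 1 stood apart from siNC replicates 2 and 3 on both leading principal components, at -26.7 against -11.7 and -10.8 on the first, which held 54.8% of the variance, and at 15.0 against -10.7 and -14.0 on the second, which held 19.3%. Across genes, the log2 fold change correlated with gene length (Spearman's rho 0.209) and with GC content (rho -0.27), and without siNC replicate 1 these values were 0.144 and -0.0524. Genes are not independent replicates, so no p is attached to these correlations. Counts of several gene groups are also given without this library.

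Ligands of EGFR and feedback genes of the ERK kinases that act below the receptor were higher in siSetdb1. Of 21 tested members, 13 rose, 1 fell and 7 did not pass, and adjusted over the list alone 16 rose and 1 fell. The ERK phosphatase genes Dusp5 and Dusp6 rose from 9.65 ± 0.90 to 33.3 ± 7.5 FPKM and from 51.7 ± 4.1 to 103.3 ± 8.4 FPKM (log2 fold change 1.67 and 0.99, adjusted p = 0.00151 and 0.00127). The EGFR ligand gene Areg rose from 13.1 ± 1.6 to 29.8 ± 5.2 FPKM (log2 fold change 1.12, adjusted p = 0.00362). Fos, an immediate-early gene outside the list, rose from 2.82 ± 0.12 to 11.1 ± 1.1 FPKM (log2 fold change 1.66). The median log2 fold change of the list was 0.54 (camera adjusted p = 3.12e-09), with an adjusted p = 0.481 with an estimated correlation. Without siNC replicate 1 the list again had 13 members higher and 1 lower, and with no filter 12 higher and 0 lower. The ligand gene Ereg, chosen after its values were seen, rose from 3.52 ± 0.88 to 6.42 ± 1.16 FPKM (limma adjusted p = 0.03). Its adjusted p was 0.0789, 0.1001 and 0.0828 without siNC replicate 2 and siSetdb1 replicates 2 and 3.

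Inflammatory genes that NF-kB is known to control were lower. Of 23 tested members, 14 fell, 1 rose and 8 did not pass, and adjusted over the list alone 18 fell and 1 rose. Beside Ccl2, the macrophage growth factor gene Csf1 fell from 33.1 ± 5.0 to 11.2 ± 0.8 FPKM (log2 fold change -1.48), the adhesion molecule gene Vcam1 from 4.31 ± 0.13 to 1.62 ± 0.05 FPKM (-1.02), and Nfkbia, the gene of the NF-kB inhibitor that NF-kB itself induces, from 82.3 ± 9.7 to 38.0 ± 4.5 FPKM (-1.10, adjusted p = 0.0022). The chemokine genes Ccl20 and Cxcl5 fell from 5.81 to 0.969 FPKM and from 33.4 to 12.5 FPKM. For Cxcl5 the adjusted p of 0.034 became 0.0897, 0.081, 0.116 and 0.108 without siNC replicate 1, siNC replicate 3, siSetdb1 replicate 1 and siSetdb1 replicate 2. The list had a median of -0.56 (camera adjusted p = 1.08e-07), and an adjusted p = 0.632 with an estimated correlation. The number that fell was 13 without siNC replicate 1, 9 without siSetdb1 replicate 1, 8 without siSetdb1 replicate 2 and 9 without siSetdb1 replicate 3.

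Secreted and metabolic products of hepatocytes that passed the filter on low values were lower as a group. Of 52 listed genes, 16 were tested. Of these 16, 10 fell, none rose and 6 did not pass, and adjusted over the list alone 13 fell. With no filter 40 were tested, of which 7 fell and none rose, and their median log2 fold change was -0.0366. Hpx, a heme carrier, fell from 7.03 ± 0.82 to 1.63 ± 0.24 FPKM (log2 fold change -1.61, adjusted p = 0.000606), and the bile canalicular transporter gene Abcc2 fell from 3.57 ± 0.28 to 1.29 ± 0.09 FPKM (-1.0, adjusted p = 0.0012). Trf, the gene of the iron carrier transferrin, fell from 23.8 ± 4.2 to 8.67 ± 2.88 FPKM. Ttr, the gene of the thyroid hormone carrier transthyretin, fell from 27.5 ± 10.5 to 7.02 ± 4.69 FPKM (-1.91, adjusted p = 0.0247), and Hp, the gene of haptoglobin, from 11.1 ± 3.5 to 2.79 ± 1.59 FPKM (-1.71, adjusted p = 0.0166). The adjusted p of Ttr was 0.0664, 0.0605, 0.0907 and 0.0864 without siNC replicate 1, siNC replicate 3, siSetdb1 replicate 1 and siSetdb1 replicate 2, and that of Hp was 0.0514, 0.0645 and 0.0514 without siNC replicate 1, siSetdb1 replicate 1 and siSetdb1 replicate 2. The median of the 16 tested members was -1.17 (camera adjusted p = 1.99e-08), with an adjusted p = 0.632 with an estimated correlation, and 8 members fell without siNC replicate 1.

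Some transcription factors of hepatocytes passed the test, as did 1945 of all 12846 genes tested. Of 15 tested members, 3 fell, 1 rose and 11 did not pass, and adjusted over the list alone 6 fell and 1 rose. Esrra, an estrogen-related receptor gene, fell from 16.8 ± 1.9 to 10.6 ± 0.8 FPKM (log2 fold change -0.61, adjusted p = 0.00825). The list median was -0.21 (camera adjusted p = 0.0423), with an adjusted p = 0.807 with an estimated correlation and 0.0587 with fry. The list test gave adjusted p = 0.0704, 0.0509, 0.0566 and 0.0936 without siNC replicate 1, siNC replicate 2, siSetdb1 replicate 1 and siSetdb1 replicate 2, and 0.0802 with trends in GC content and length removed. The number that fell was 2 without any 1 of the siNC libraries or siSetdb1 replicate 3, 1 without siSetdb1 replicate 1 or 2, and 1 with these trends removed, and none rose without siNC replicate 2 or 3 or any 1 siSetdb1 library. Of 13 markers of biliary and progenitor cells, 5 rose, 2 fell and 6 did not pass, and adjusted over the list alone 6 rose and 3 fell. Sox9 and Klf5, transcription factors of the bile duct lineage and of epithelia, rose from 4.95 ± 0.44 to 9.26 ± 1.49 FPKM and from 11.6 ± 0.8 to 19.8 ± 1.4 FPKM, the integrin gene Itga6 rose from 12.6 ± 0.7 to 22.0 ± 1.0 FPKM, and the receptor gene Fgfr2 fell from 3.04 ± 0.30 to 0.899 ± 0.210 FPKM. This list was not called by camera (adjusted p = 0.0783, and 0.632 with an estimated correlation) and was by fry (adjusted p = 0.0307).

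**Figure D3:**
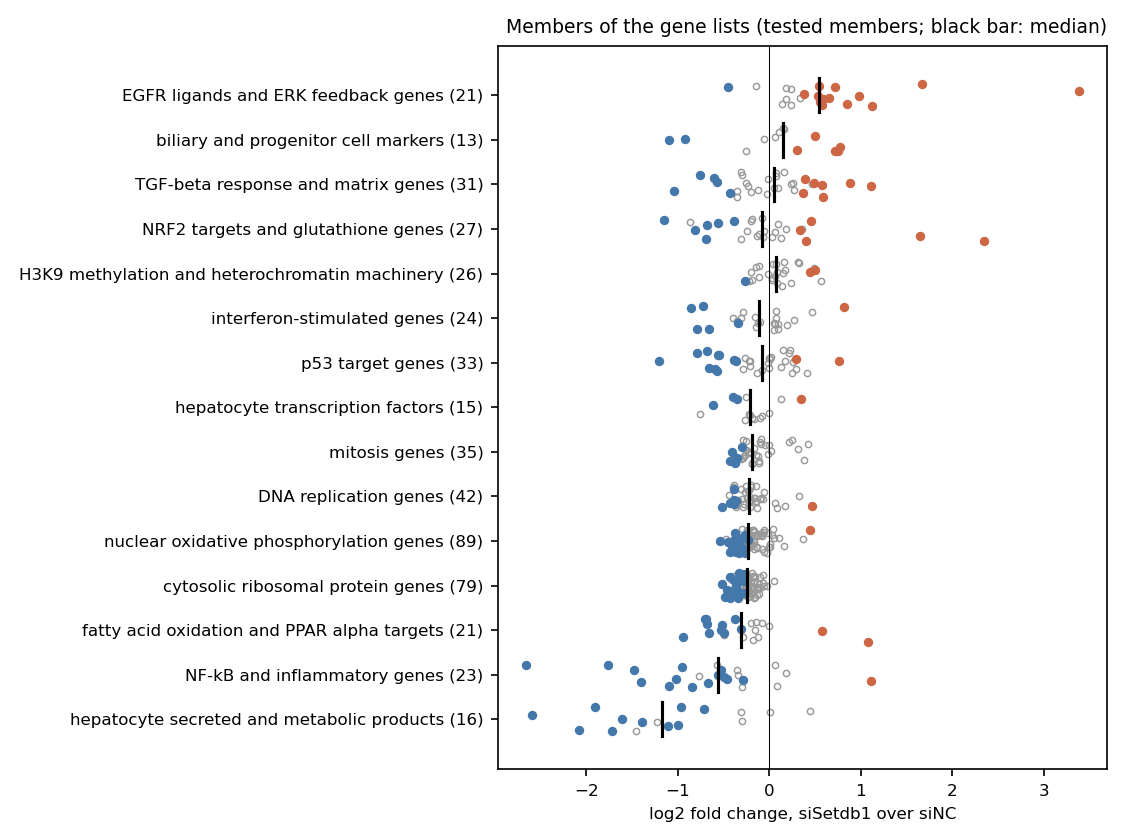
Log2 fold change of siSetdb1 over siNC for the tested members of 15 of the fixed gene lists, with filled points for members that passed the test over all genes, open points for the rest, a black bar for the list median and the number of tested members in brackets. The EGFR and ERK list lies to the right of 0 (median 0.54) and the hepatocyte product and NF-kB lists to the left (medians -1.17 and -0.56).

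Genes of fatty acid oxidation and targets of PPAR alpha were lower, with 10 of 21 tested members falling, 2 rising and 9 not passing. Adjusted over the list alone, 12 fell and 2 rose. Cpt1a, which encodes the enzyme that controls fatty acid entry into mitochondria, fell from 28.3 ± 2.0 to 17.3 ± 1.4 FPKM (log2 fold change -0.68, adjusted p = 0.00362). The thioesterase gene Acot1 and the thiolase gene Acaa2 fell by 0.94 and 0.70 on the log2 scale. Vnn1, a pantetheinase gene, rose from 3.13 ± 0.22 to 7.77 ± 0.77 FPKM. The list median was -0.31 (camera adjusted p = 0.000164), with an adjusted p = 0.648 with an estimated correlation. The number that fell was 11 without siNC replicate 1, 6 without siSetdb1 replicate 1 and 5 without siSetdb1 replicate 2. Of 21 genes of fatty acid and triglyceride synthesis, 4 fell and 1 rose, and adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 0.0983). The desaturase gene Scd1 fell from 313 ± 19 to 199 ± 34 FPKM and the lipin gene Lpin2 from 9.06 ± 0.52 to 6.04 ± 0.53 FPKM. None of these 21 genes rose without siNC replicate 2 or 3 or any 1 siSetdb1 library, and 2 fell without siSetdb1 replicate 1 or 2. Of 25 cholesterol synthesis genes, 1 rose and 1 fell, and adjusted over the list alone 1 fell and none rose. The gene that fell was the sterol isomerase gene Ebp (log2 fold change -0.40), and its adjusted p was 0.0745, 0.0753 and 0.0535 without siSetdb1 replicates 1, 2 and 3. No gene of this list rose without siNC replicate 2 or 3 or any 1 siSetdb1 library.

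Ribosomal protein genes and nuclear genes of oxidative phosphorylation were lower by a small amount. Of 79 tested ribosomal protein genes, 23 fell, none rose and 56 did not pass, and adjusted over the list alone 39 fell. The median was -0.24 (camera adjusted p = 1.9e-12), with an adjusted p = 0.632 with an estimated correlation. Rpl31 fell from 378 ± 24 to 270 ± 9 FPKM (log2 fold change -0.48, adjusted p = 0.00686). Reads in ribosomal protein genes made up 4.21% ± 0.28 of the reads in siNC and 3.53% ± 0.07 in siSetdb1, those in pseudogenes 2.66% ± 0.17 and 2.34% ± 0.05, and those in ribosomal RNA 0.020% ± 0.002 and 0.012% ± 0.002, with no overlap between the groups in any of these 3 shares. Many ribosomal protein genes have processed pseudogenes with which short reads can be shared. Of 89 tested oxidative phosphorylation genes, 18 fell, 1 rose and 70 did not pass, and adjusted over the list alone 38 fell and 2 rose. The median was -0.23 (camera adjusted p = 1.33e-08), with an adjusted p = 0.648 with an estimated correlation. The complex III gene Uqcr10 fell from 133 ± 14 to 91.2 ± 5.4 FPKM (log2 fold change -0.54) and had an adjusted p of 0.051 and 0.0511 without siSetdb1 replicates 1 and 2. Without siNC replicate 1, 19 ribosomal protein genes and 19 oxidative phosphorylation genes fell. The ribosomal protein count was 3, 1, 2 and 6 without siNC replicate 2 and siSetdb1 replicates 1, 2 and 3, and 14 with median-ratio scaling. The oxidative phosphorylation count was 6, 1, 2 and 11 without the same 4 libraries. Of 15 genes of the mitochondrial genome, 1 fell by the test over all genes, the transfer RNA gene mt-Tp (-0.33, adjusted p = 0.0388), and adjusted over the list alone none passed. The adjusted p of mt-Tp was 0.116, 0.0568, 0.097, 0.0933 and 0.11 without siNC replicates 2 and 3 and siSetdb1 replicates 1, 2 and 3.

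Some genes of DNA replication and mitosis fell, as did 1062 of all 12846 genes tested. Of 42 DNA replication genes, 6 fell, 1 rose and 35 did not pass, and adjusted over the list alone 9 fell and 1 rose. Gins2, of the replicative helicase, fell from 5.01 ± 0.42 to 3.19 ± 0.32 FPKM (log2 fold change -0.52), with an adjusted p of 0.0552 without siSetdb1 replicate 1, and the transcription factor gene E2f2 rose from 3.85 ± 0.08 to 5.74 ± 0.52 FPKM (0.47). The median was -0.22 (camera adjusted p = 9.33e-05), with an adjusted p = 0.832 with an estimated correlation and 0.196 with fry. Of 35 mitosis genes, 5 fell, none rose and 30 did not pass, and adjusted over the list alone 7 fell. The checkpoint kinase gene Bub1b fell from 25.3 ± 1.6 to 18.5 ± 0.9 FPKM (-0.43). The median was -0.18 (camera adjusted p = 0.0131), with an adjusted p = 0.832 with an estimated correlation, 0.347 with fry, and adjusted p = 0.194 and 0.144 without siNC replicate 2 and siSetdb1 replicate 3. The number of replication genes that fell was 5 without siNC replicate 1, 1 without siNC replicate 2 or siSetdb1 replicate 3, and 0 without siSetdb1 replicate 1. The number of mitosis genes that fell was 7 without siNC replicate 1, 3 without siSetdb1 replicate 2, and 1 without siNC replicate 2, siSetdb1 replicate 1 or siSetdb1 replicate 3.

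Targets of p53 moved in both directions. Of 33 tested members, 10 fell, 2 rose and 21 did not pass, and adjusted over the list alone 12 fell and 6 rose (median -0.07, camera adjusted p = 0.295). Trp53inp1, a stress-response gene, fell from 29.9 ± 6.1 to 12.4 ± 2.0 FPKM (log2 fold change -1.20), the death receptor gene Tnfrsf10b fell from 6.49 ± 0.45 to 4.06 ± 0.19 FPKM, and the ephrin receptor gene Epha2 rose from 33.9 ± 3.2 to 58.1 ± 4.8 FPKM. Of 16 cell cycle inhibitors and senescence markers, 4 fell and 2 rose, and adjusted over the list alone 6 fell and 2 rose (camera adjusted p = 0.785). Igfbp3 rose from 9.0 ± 0.24 to 16.9 ± 0.9 FPKM and Gdf15 fell from 3.79 ± 0.17 to 2.05 ± 0.34 FPKM. Of 28 apoptosis regulators, 4 fell and 2 rose, and adjusted over the list alone 7 fell and 4 rose. For this list the adjusted p was 0.651 with camera, 0.832 with camera with an estimated correlation, and 0.0307, downwards, with fry. The proapoptotic gene Bid fell by 0.64 on the log2 scale, and Cflar, an inhibitor of caspase 8, rose by 0.56. Without siNC replicate 1, 11 p53 targets fell and 4 rose, 4 senescence markers fell and 4 rose, and 5 apoptosis regulators fell and 4 rose. Without siSetdb1 replicates 1, 2 and 3 the number of p53 targets that fell was 6, 5 and 6, and that of senescence markers was 1, 1 and 3. Only 1 apoptosis regulator rose without siSetdb1 replicate 2.

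Listed genes of the silencing machinery around SETDB1, and listed classes that SETDB1 is known to silence, showed few changes among tested genes. Resf1, which rose by 2.04 on the log2 scale, is not in the machinery list. The filter left most listed genes of some of these classes untested, and retroelements, which no list covers, were not examined. Of 26 genes of the H3K9 methylation and heterochromatin machinery, 2 rose, 1 fell and 23 did not pass, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.225). When siNC replicate 1 was left out, 3 rose and none fell. Beside Atf7ip, Pphln1, a subunit of the HUSH silencing complex, rose by 0.45 and the methyltransferase gene Ehmt2 fell by 0.27 on the log2 scale (adjusted p = 0.0468). Pphln1 had an adjusted p of 0.0661 without siSetdb1 replicate 2, and Ehmt2 had adjusted p values of 0.0504, 0.109, 0.145, 0.156 and 0.0967 without siNC replicates 1 and 2 and siSetdb1 replicates 1, 2 and 3. Of 256 zinc finger genes that passed the filter, 2 rose and 7 fell, and adjusted over the list alone 1 fell and none rose (camera adjusted p = 0.205). Zfp637 fell from 13.8 ± 1.0 to 6.54 ± 0.27 FPKM (-0.97, adjusted p = 0.00105). Of 39 listed imprinted genes, 11 were tested. Among these 11 the mannose 6-phosphate receptor gene Igf2r fell by 0.51 on the log2 scale, also adjusted over the list alone, and the others did not pass (camera adjusted p = 0.866). Its adjusted p was 0.0543, 0.0565, 0.0802 and 0.0555 without siNC replicate 3 and siSetdb1 replicates 1, 2 and 3. Of 43 listed clustered protocadherin genes, 8 were tested. None of the 8 passed over all genes or adjusted over the list alone (camera adjusted p = 0.785), and the one with the highest value, Pcdhb16, had 3.44 ± 0.46 and 3.85 ± 0.12 FPKM. Of 48 listed genes of germ cells and the early embryo, 2 had high enough values to be tested, and neither passed. Xlr4b had 1.08 ± 0.22 and 1.31 ± 0.11 FPKM. The number of zinc finger genes that rose was 3, 2, 4, 0, 0 and 1, and the number that fell was 11, 2, 4, 3, 1 and 2, without siNC replicates 1, 2 and 3 and siSetdb1 replicates 1, 2 and 3. With limma-voom 8 rose and 11 fell, with the variance trend on reads 6 and 10, with median-ratio scaling 4 and 5, and with GC and length trends removed 11 and 13. With no filter 0 rose and 2 fell, a count over the same 256 genes that includes no zinc finger gene below the filter.

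The tested interferon-stimulated genes did not rise as a group. Of 53 listed genes, 24 were tested. Of these 24, 5 fell, 1 rose and 18 did not pass, and adjusted over the list alone 8 fell and 2 rose (median -0.11, camera adjusted p = 0.321). With no filter 49 were tested, of which 3 fell and 1 rose. Cxcl10 and Ifit2 fell from 2.18 ± 0.44 to 0.752 ± 0.179 FPKM and from 3.24 ± 0.52 to 1.46 ± 0.30 FPKM, and Oasl1 rose from 3.45 ± 0.47 to 6.84 ± 0.87 FPKM. Of 12 nucleic acid sensors and adaptors, 2 fell and 1 rose over all genes and adjusted over the list alone (camera adjusted p = 0.785). Tmem173, which encodes the adaptor STING, fell from 2.66 ± 0.31 to 1.13 ± 0.12 FPKM (log2 fold change -0.78, adjusted p = 0.00368). No sensor or adaptor gene rose without siNC replicate 3 or any 1 siSetdb1 library, and 1 fell without siSetdb1 replicate 1. Without siNC replicate 1, 5 interferon-stimulated genes fell and 2 rose, and without siNC replicate 3 and siSetdb1 replicates 1, 2 and 3 the number that fell was 3, 2, 2 and 3.

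Genes of the TGF beta response and of the matrix moved in both directions. Of 31 tested members, 7 rose, 5 fell and 19 did not pass, and adjusted over the list alone 9 rose and 9 fell (camera adjusted p = 0.785). The collagen gene Col5a1 rose from 0.508 ± 0.108 to 2.27 ± 0.35 FPKM, Smad7, an inhibitor of the pathway, rose from 7.65 ± 0.71 to 15.0 ± 1.5 FPKM, and Id3 fell from 10.4 ± 1.3 to 4.56 ± 0.24 FPKM. Among 27 targets of NRF2 and glutathione genes, 5 rose, 6 fell and 16 did not pass, and adjusted over the list alone 6 rose and 9 fell. Beside Gsta1 and Gsta2, which rose, Gstm1 and Mgst1 fell by 1.15 and 0.69 on the log2 scale. The median of this list was -0.08 and camera pointed down (adjusted p = 0.785), whereas fry pointed up (adjusted p = 0.709). Of 34 genes of the integrated stress response and the unfolded protein response, 4 rose and 4 fell, and adjusted over the list alone 8 rose and 8 fell (camera adjusted p = 0.866). The amino acid transporter gene Slc7a5 and the pseudokinase gene Trib3 rose by 0.44 and 0.50. Of 8 Wnt targets, 2 rose and 1 fell, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.866), with Lect2 rising from 9.43 ± 0.70 to 14.9 ± 1.0 FPKM. Of 8 markers of fetal liver and liver tumours, 2 rose and 1 fell over all genes and adjusted over the list alone (camera adjusted p = 0.698). Igf2bp2, an RNA-binding protein gene, fell from 14.4 ± 0.1 to 8.15 ± 0.61 FPKM. The number of TGF beta and matrix genes that rose was 3 and 4 without siNC replicates 2 and 3, and 2 without any 1 siSetdb1 library. Without siSetdb1 replicate 1, 2 NRF2 and glutathione genes rose and 2 fell, and no stress response gene fell without siNC replicate 2 or siSetdb1 replicate 1 or 2. Of the fetal liver and tumour markers, 1 rose without siSetdb1 replicate 1 and none without siSetdb1 replicate 2, and of the Wnt targets none fell without siSetdb1 replicate 1 and 1 rose without siSetdb1 replicate 2.

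Markers of other liver cell types were mostly below the filter. Of 16 macrophage and leukocyte markers, 2 were tested and both fell, also adjusted over the list alone. Cd68 fell from 5.27 ± 1.07 to 2.48 ± 0.46 FPKM and Cd14 from 49.0 ± 5.2 to 37.8 ± 3.5 FPKM. Cd14 did not pass in any of the 6 fits that left out 1 library (adjusted p = 0.0508 to 0.155), and Cd68 had an adjusted p of 0.0516 without siSetdb1 replicate 2. Of 15 markers of stellate cells and fibroblasts, 2 were tested and 1 fell, also adjusted over the list alone, the matrix gene Postn from 2.97 ± 0.70 to 1.32 ± 0.11 FPKM, with an adjusted p of 0.0519 without siSetdb1 replicate 1. Of 13 endothelial markers, 3 were tested and none passed over all genes or adjusted over the list alone. Flt1 had 0.857 ± 0.046 and 0.896 ± 0.106 FPKM. Of the 27 lists with at least 5 tested members, camera with a preset correlation called 9, fry called 8, and none was called with an estimated correlation.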

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

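The count below was chosen only after the data had been opened, and its limits on reads were not part of the plan. Among the 12570 genes left out by the filter on low values, 13 had at most 3 reads in all siNC libraries together and at least 5 reads in each siSetdb1 library, a signal outside the tested genes that lies above its level in the control libraries. In the opposite direction 8 genes met the same limits, and whether 13 differs from 8 was not tested. The first set held the vomeronasal receptor gene Vmn1r42 (chromosome 6, 89842573 to 89876413, mm10), with 0, 1 and 1 reads in siNC and 9, 13 and 7 reads in siSetdb1, and its neighbouring pseudogene Vmn1r-ps28 (89907677 to 89908618), with 0, 0 and 1 against 9, 7 and 6 reads. The tested gene Vmn1r40 on the same chromosome (89707540 to 89716657), chosen after its values were seen, rose from 0.220 ± 0.052 to 1.80 ± 0.32 FPKM (log2 fold change 1.19, limma adjusted p = 0.00151). These receptor genes form a multigene family, and the assignment of 50-base reads to 1 member is uncertain. Others in the first set were Selp, with 0, 2 and 0 reads against 11, 10 and 5, P2ry14, with 0, 1 and 0 against 9, 8 and 7, and Sycp1-ps1, a processed pseudogene of a meiotic gene, with 1, 0 and 1 against 6, 9 and 11. The second set held Ifit3b, with 7, 12 and 11 reads in siNC against 1, 0 and 0 in siSetdb1, and Pak3, with 6, 13 and 12 against 1, 1 and 0. No technical or biological explanation was tested for these counts.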

How the results depend on the processing

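The tests with median-ratio or upper-quartile scaling and with the variance trend on reads were chosen only after the result was seen, as were those of Setdb1, 2-fold changes, gene lists and named genes with GC and length trends removed. Setdb1 fell and passed under each of the 16 other settings run (adjusted p at most 0.0133, with the replicate block), and each of the 1945 genes that passed had the same sign wherever it was tested. Each setting used the same libraries or all but 1 of them. For genes picked by their difference in these libraries, an unchanged sign was therefore likely in advance. With no filter, which adjusts over 25416 genes, 890 genes passed, 460 higher and 430 lower. At an adjusted p of 0.01, 529 passed. Changes of at least 2-fold numbered 273 with a pseudocount of 0.1 and 293 with limma-voom. A pseudocount of 0.1 shrinks low genes less, and for limma-voom, which also changes unit and weights, the cause was not tested. With trends in GC content and length removed, 1450 genes were higher (1776 of the 1945 were shared), and the cause was not tested. With the variance trend on reads 2258 genes passed (1887 shared), and with the 2 scalings 1926 and 1882. Leaving out 1 library, which leaves fewer samples, gave 683 (without siSetdb1 replicate 2) to 2176 genes (without siNC replicate 1), 355 to 1101 higher and 326 to 1075 lower. It gave 689, 978, 1060 and 1402 genes without siSetdb1 replicates 1 and 3 and siNC replicates 2 and 3. Of the 27 gene lists 0 were called with an estimated correlation, 8 with fry, and 7 to 10 without 1 library.

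The replicate block gave 1015 genes, 480 higher and 535 lower. Across all tested genes, libraries with the same number did not deviate together (correlations of -0.157, 0.167 and -0.172), and 1 of the 3 correlated best with its own number, so the numbers were not taken to pair the samples. Some hepatocyte products nevertheless had the same order of the numbers in both groups. Ttr was at 27.2, 17.2 and 38.1 FPKM in siNC replicates 1 to 3 and at 4.49, 4.15 and 12.4 FPKM in siSetdb1. Alb, Apoa1, Hp, Hpx and Trf shared this order, whereas Gc, C3, Abcc2, Apob and Cyp27a1 did not. Whether the numbers pair the samples for such genes stays open.

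Of 2110 results for 132 other genes picked by the naming rule or after their values were seen, 1890 kept their direction and side of the threshold, 212 (49 genes) no longer passed, 8 (3 genes) newly passed and none changed direction, again in fits to the same libraries. Of 123 such genes that passed, 48 did not pass without at least 1 of the 6 libraries. The planned edgeR and DESeq2 settings were not run, because the deposited values are FPKM, and limma-voom was the fit run on recovered reads. Depth limits genes with few reads, since 1 read over 1 kb of exon was worth 0.0561 to 0.0596 FPKM.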

Other observations

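The term tests, the tests of EGFR and ERK genes without siNC replicate 1 and without GC and length trends, the test of a smaller share of hepatocyte-like cells, the counts of neighbouring genes, and the genes Itga2, Itgav, Itgb4, Lamb3, Ccl7, Ccl9, Hbegf, Junb, Klf6, Gadd45b, Alb, Apoa1, Apob and Cyp27a1 were chosen only after the results were seen. Genes that rose included more adhesion genes than chance gives. The process "cell adhesion" held 31 risen genes among 147 tested, against 10.4 by chance (one-sided Fisher's exact test, adjusted p = 4.54e-05 over 2980 tests of 1490 terms in both directions), while the median log2 fold change of the 147 was 0.0348. The integrin genes Itga2, Itgav and Itgb4 rose from 32.3 ± 4.6 to 56.9 ± 3.1, from 24.0 ± 1.9 to 39.1 ± 2.3 and from 12.6 ± 1.8 to 20.9 ± 0.4 FPKM. The laminin gene Lamb3 rose from 84.3 ± 7.9 to 126 ± 4 FPKM. The process of cell-substrate adhesion had 8 risen genes among 19 (exact adjusted p = 0.00776, with 0.0222 once GC and length trends were removed and 0.0796 without siNC replicate 1).

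Of the 1490 terms, tyrosine dephosphorylation had the highest ratio of risen genes to those expected, with 11 of 20 genes risen against 1.42 by chance (exact adjusted p = 4.54e-05), 8 of them of the Dusp phosphatase family. Angiogenesis had 29 of 137 genes (exact adjusted p = 7.75e-05). Among processes with more fallen genes than chance, neutrophil chemotaxis had 8 of 19 (exact adjusted p = 0.0181, with 0.0195 without siNC replicate 1 and 0.106 with GC and length trends removed). Its chemokine genes Ccl7 and Ccl9 fell from 1.89 ± 0.10 to 0.504 ± 0.15 and from 10.0 ± 1.3 to 4.74 ± 0.26 FPKM. Genes within a term do not vary independently, so these p-values are too small.

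The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1945 genes and the highest other 0, and the counts of 2-fold changes were 98 and 0, so that 1 split, the real one, had a count as large in both cases. With limma, the other splits had 128 to 535 genes at an unadjusted p under 0.05, against 4141 in the real one. Each other split mixes the 2 groups, which adds the group difference to the residual spread and lowers these counts. They are therefore not the level that chance would give. For gene lists called by camera the real split gave 9 and the highest other 12, and 3 of the 10 splits, the real one included, had 9 or more.

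Ribosomal protein and oxidative phosphorylation genes were lower together (168 members, median log2 fold change -0.236). If trends with GC content and length were the whole cause, the median would shrink to near 0 once they were removed, but it was -0.167 (95% bootstrap interval over genes -0.188 to -0.142). Without siNC replicate 1 it was -0.201 (-0.225 to -0.174), which argues against that library as the whole cause, while the trends may account for part of the shift. These intervals treat the genes as independent and do not measure the spread between samples. Reads shared with pseudogenes and the correlation between such genes stay open, as does the Setdb1 knockdown itself.

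Of the EGFR ligand and ERK feedback genes, all 13 members that rose also rose without siNC replicate 1, and all 13 with GC content and length trends removed, which argues against both as the cause. The ligand gene Hbegf rose from 8.27 ± 0.87 to 13.6 ± 1.3 FPKM. A general immediate-early response at harvest was tested on 21 other such genes, of which 10 rose, among them Junb (130 ± 12 to 210 ± 29 FPKM) and Klf6, and 1, Gadd45b, fell. Their median of 0.335 (95% bootstrap interval over genes 0.0994 to 0.465) lay between the values set for and against that explanation. A general response and one of the EGFR and ERK genes alone therefore cannot be told apart, and off-target effects of the siRNA were not tested.

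The tested hepatocyte products were lower as a group, and without siNC replicate 1 their median was -1.21 (95% bootstrap interval over members -1.6 to -0.628, against -1.17), which argues against that library as the cause. This interval, too, does not measure the spread between samples. A smaller share of hepatocyte-like cells would lower the abundant members by 1 common factor. With library means removed, 10 of them differed in their fall (F of member by group 6.48, against 2.15 passed by chance in 5% of cases). That limit holds for members of equal and independent spread, whereas the SE of their log2 ratios ran from 0.0856 (Cyp27a1) to 0.738 (Alb). The F therefore argues only weakly against a smaller share as the whole cause. This F was at least 4.95 without any 1 member and at least 3.63 without any 1 library. The highest in the other splits of the samples, which mix the 2 groups, was 4.07. The SD of the log2 ratios (0.866, 95% bootstrap interval over members 0.407 to 1.13) did not settle the question against 2 times the median SE (0.765). A share that fell in part, products that other cells also make, lower expression per cell and off-target effects of the siRNA stay open.

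Among hepatocyte products that did not pass, Alb was at 7.93 ± 5.54 and 2.61 ± 1.65, Apoa1 at 22.9 ± 8.2 and 8.38 ± 5.75, Apob at 7.83 ± 3.44 and 10.3 ± 1.3 and Cyp27a1, the only 1 of the 4 whose groups did not overlap, at 6.22 ± 0.49 and 4.90 ± 0.31 FPKM in siNC and siSetdb1. Under other settings some of them passed with limma: Alb and Apoa1 with the replicate block (adjusted p = 0.0101 and 0.0203), also with trends removed, Apoa1 without siSetdb1 replicate 3 (0.0231) and with a filter of 1 CPM (0.0417), and Cyp27a1 with that filter (0.0464) and with the variance trend on reads (0.0472).

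A further hypothesis was that changed genes lie near each other. Of the 883 genes that rose, 148 had another such gene of a different family within 100 kb, against a median of 107 in 1000 draws matched on expression, number of neighbours and GC content (permutation p = 0.001, the smallest these draws can give). With draws matched on expression alone the median was 151 (permutation p = 0.6). For the splits of the samples the 883 highest and 1062 lowest genes by t were taken in each, with draws of their own. On that count the real split had 150 against 110, an excess of 40, and the highest other 54, or 63.5 and 38 with trends in GC content and length removed. Of the 1062 genes that fell, 318 had such a neighbour against 264 (permutation p = 0.001, again the smallest). In the splits the real one had 318 against 262, an excess of 56, and the highest other 40, but with these trends removed they had 24 and 38, so neither direction was settled.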
